A study of Aplysia californica with 8 samples.

How the data were processed

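Total RNA from pleural ganglia of 8 trained and 8 control animals, by the series design, was hybridised to 8 two-colour Agilent oligonucleotide arrays. The labels give 15 distinct animal numbers, as number 789 appears in both groups. Spots were read as the mean intensity of each channel and the median intensity of its local background, unnormalized, per the file headers, by Agilent's Feature Extraction software (version 11.5.1.1). Its processed signals, also intensities, were background-subtracted, detrended and dye-normalized by that software, and its log10 ratios were made from them, per the file headers. The log10 ratios were read but not tested. The authors also deposited a table of log2 ratios, 1 column per array, made with limma per the submitters' processing notes, with no version given. Each column of that table was set against log2 Cy5 over Cy3 of its own array, as computed here from the scanner values by the steps below. Over the probes tested it followed those ratios (r from 0.978 to 0.991 across probes, slope from 1.09 to 1.13). Slopes above 1 mean that the ratios computed here were somewhat smaller than the deposited ones. Its medians, over spots that are not controls, were 0.005 (replicate 1), 0.007 (replicate 2), 0.006 (replicate 3), 0.003 (replicate 4), 0.004 (replicate 5), 0.005 (replicate 6), 0.007 (replicate 7) and 0.009 (replicate 8). Its scale, centring near 0 and direction (Cy5 over Cy3, not turned by training) follow from this, and its background and normalization steps are not given in the sources used here. The remaining columns used were 0 or 1 flags set by the scanner software, per the file headers.

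Each array held 62976 spots, of which 61657 were not controls, standing for 61615 probes of 60 bases, 50354 distinct sequences and 26091 gene names, mostly EST accessions. The mean signals were background-corrected with normexp (offset 50) and normalized within each array by loess, with control and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3. No non-control spot was saturated, and 0 to 3 per array had an outlier flag and were left out. Spots of one probe were averaged. A probe was tested if it was well above background on at least 4 of the 8 arrays in the trained or in the control channel and had values on at least 6 arrays, 3 of each dye orientation. This left 38970 probes, and 22645 were not tested. The log2 ratio of Cy5 over Cy3 was regressed on the direction of training (trained in Cy5 or in Cy3) with a term for the dye, by lmFit and eBayes, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. The prior had 2.77 degrees of freedom. Standard errors are those of the moderated fit, and the median over probes was 0.09.

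Spike-in controls, as evaluated by the scanner software per the file headers, had slopes of observed on expected log ratio of 0.824 (replicate 8) to 0.910 (replicate 7), so ratios were somewhat compressed. Signal over background sets the limit on dim transcripts, which have no useful ratio.

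Names came from the files. Of the accessions, 2 matched the RefSeq table of the assembly AplCal3.0 (LOC100861465 and dar1). The design names neuropeptide precursor, apnalcn and ACN4PKA were used as given. Otherwise a probe was named if its description gave an animal protein with a function, on a sequence that the design does not mark as reversed, which with the former made 44 probes, 30 of them tested. These descriptions are old best matches in other species with no measure of similarity, and they are not identities. No genome coordinates are given. The rule for naming genes, fixed before the data were examined, took all named genes past the threshold, the named genes with the smallest p up to 12 per direction, up to 3 members per list, cornichon and the reference genes whatever their values, and at most 2 unnamed probes per direction. A gene with several probes was shown by its brightest probe. Which descriptions counted as a name was decided afterwards, when the files had been seen, and ACN4PKA was added because of its own name.

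The 24 gene lists were search patterns for gene names and descriptions, and unlike the named genes they also took sequences that the design marks as reversed. A list was tested with limma's camera (preset correlation of 0.01, 1 probe per gene, 18259 genes) if it had at least 3 measured genes, with fry beside it. The fit was tested on simulated data with 200 probes moved by known amounts and on the measured ratios with the same amounts added. In the measured ratios, 8 of the 38770 probes without an added amount passed the threshold.

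Alternatives fixed before the data were examined were no background correction, a normexp offset of 16, the processed signals, median centring, the deposited table, no filter or a stricter filter on dim probes, outlier spots kept, no dye term, the direction as the labelling text reads, slide row as a term or each row alone, array weights, an intensity trend with a robust prior, looser thresholds, each array left out in turn, the mean of all probes of a gene, and an estimated correlation or ranks for the lists. Added after seeing the data were averages over identical sequences and over gene names, the step in animal number as a term, and fits without replicates 1 and 5 or without replicates 1 and 3. For the single-channel profiles, arrays were scaled to each other by Aquantile in limma and each probe was centred within each dye. Animal numbers were read from the labels in the order Cy3, Cy5, which matches their letters for control and trained. The labels use number 789 both for the trained animal of replicate 1 and for the control animal of replicate 5.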

Results

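Gene expression was measured in the pleural ganglia of the marine mollusc Aplysia californica 24 hours after the end of training for long-term habituation, a lasting weakening of the siphon withdrawal reflex produced by days of repeated brushing of the skin. Each of 8 arrays compared RNA from 1 trained animal with RNA from 1 control animal that had been matched to it on the duration of its reflex before training. The trained animal was labelled with the red dye Cy5 on 4 arrays (replicates 1, 3, 4 and 6) and with the green dye Cy3 on the other 4 (replicates 2, 5, 7 and 8), according to the channel labels. The text on the labelling procedure in the same labels reads as if trained RNA carried Cy5 throughout, and the channel labels were followed. All 8 arrays lay on 1 slide, in 2 rows of 4. Trained RNA was in Cy5 on replicates 1, 3 and 4 of row 1 but only on replicate 6 of row 2. Dye orientation was thus not balanced over the rows, and slide row overlaps in part with the direction of training. Of the spots that were not controls, 48.5% (replicate 8) to 63.0% (replicate 1) were well above background in Cy3, and 56.9% (replicate 6) to 62.9% (replicate 5) in Cy5. The number of arrays limited the precision.

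The comparison asks which transcripts differed between ganglia of trained and untrained animals 1 day after training. Among 25 genes with a usable name, 15 had a higher and 10 a lower mean ratio in trained animals, and 0 passed the threshold with limma (smallest adjusted p = 0.817), nor did any reach an unadjusted p under 0.05. LOC100861465 had a log2 ratio of trained over control of 0.14 (SE 0.07, adjusted p = 0.817, limma) and was higher on 7 of 8 arrays. The gene dar1 had a log2 ratio of -0.09 (SE 0.09, adjusted p = 0.869, limma) and was higher on 3 of 8 arrays. A neuropeptide precursor, from a class of genes whose products are cut into secreted signalling peptides, stood at 0.13 (SE 0.16) on its brightest probe, and was at -0.0085 without replicate 1 and 0.24 without replicate 5, so the sign on that probe rested on a single array. All 3 of its probes had positive values, and their mean stood at 0.20 (SE 0.13). ACN4PKA, whose design name refers to protein kinase A, the cAMP-dependent kinase long studied in Aplysia learning, was at 0.03 (SE 0.15), and its sign turned in 4 of 8 fits that left out 1 array (range -0.055 to 0.15). Of its 3 probes, 2 had positive values. Centring each array on its median in place of loess turned LOC100861465, the neuropeptide precursor and ACN4PKA to negative values. The sodium leak channel apnalcn was not well above background: its 3 probes reached that level on at most 1 array in trained and 3 arrays in control animals.

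Other named genes carry only the similarity that the array design gave to their sequence. The tyrosine kinase 5 and dentin sialophosphoprotein matches both had a log2 ratio of 0.18, with SE of 0.15 and 0.11, and were higher on 6 and 7 of 8 arrays. Sterolin-2 was at 0.10 and the testis protein match (T-complex-associated-testes-expressed-1) at 0.07. Ureb1, a match to a ubiquitin ligase, was at 0.05, ribosomal protein L4 at 0.03 and neurofascin (NFASC), a neural cell adhesion molecule, at 0.02. The homeodomain matches caudal and orthodenticle-2 were at 0.04 and 0.02, and Bcl9l, a cofactor of Wnt signalling, was also at 0.02. On the negative side, the scaffold protein BAI1-associated protein 1 was at -0.10, the A kinase anchor protein AKA-1, which tethers protein kinase A, at -0.09, and doublesex at -0.09. Villin, the katanin p80 subunit, which belongs to a microtubule-severing enzyme, and a sodium/hydrogen exchanger were each at -0.07. The zinc finger protein WIG-1 was at -0.06, phosphorylase phosphatase at -0.05 and DSC-2 at -0.01. None of these values passed the threshold, and for several the sign depended on the processing or a single array carried much of the value: sterolin-2 was at 0.033 without replicate 8, the testis protein at 0.021 without replicate 3 and doublesex at -0.0064 without replicate 4. Villin, katanin p80, the sodium/hydrogen exchanger, ribosomal protein L4, NFASC, orthodenticle-2 and Bcl9l were dim and did not pass the stricter filter. All of them were further from 0 with a normexp offset of 16 (villin at -0.14). With the processed signals all but NFASC (-0.0086) were further from 0 again, villin at -0.55 (SE 0.26).

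**Figure D1:**
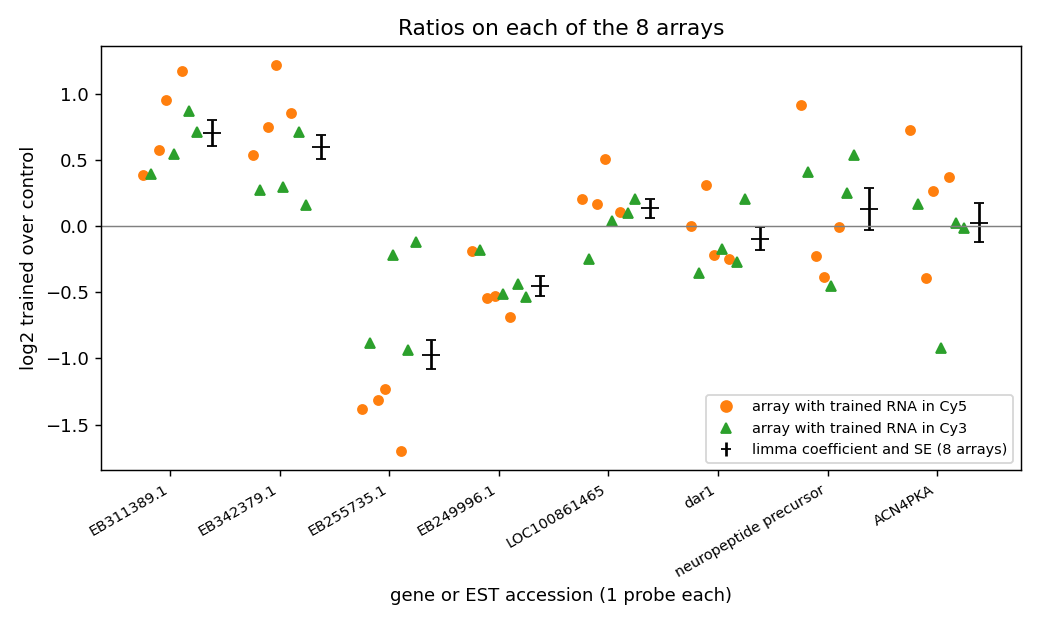
Log2 ratio of trained over control on each of the 8 arrays (points, vertical axis) for 4 EST accessions without a gene name and 4 named genes (horizontal axis), with the limma coefficient and its SE in black. All 8 arrays lie above 0 for EB311389.1 and EB342379.1 and all 8 below 0 for EB255735.1 and EB249996.1, while each of the 4 named genes has arrays on both sides of 0.

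Gene lists fixed before the data were examined could hardly be measured, because 98.5% of probes were described as unknown by the array design. Of 24 lists, 4 had a measured member and 1 had enough genes to test. The list for oxidative phosphorylation, the mitochondrial pathway that makes most ATP, had 7 measured genes, taken by description alone. Not each of them need belong to that pathway. Of these, 3 were higher and 4 lower in trained animals, 0 past the threshold over all probes and 0 when adjusted over the list alone. The match to NADH dehydrogenase subunit 4 of a flatworm was at 0.21 (SE 0.11) and higher on 7 of 8 arrays, while a match to subunit 4 of a louse was at -0.13 (SE 0.19). The match to subunit 6 of a fish was at -0.24 (SE 0.15) and higher on 2 of 8 arrays, and one to subunit 6 of a fluke was at 0.01 (SE 0.06). The match to subunit F of a plant was at -0.21 (SE 0.14), and one to ATP synthase subunit 8 of an oomycete was at -0.0015 (SE 0.06). The fluke and plant matches are on sequences that the design marks as reversed. As a group these genes did not differ from the others by limma's camera (adjusted p = 0.823, and adjusted p = 0.825 with an estimated correlation), and limma's fry, which tests whether the genes move on balance one way, gave an adjusted p = 0.415. With trained read as Cy5 on every array the list leaned the other way (fry adjusted p = 0.0016 and camera adjusted p = 0.076, limma), a reading in which dye and training cannot be told apart. The median of their log2 ratios was -0.0015 and the mean -0.042. Cytosolic ribosomal proteins had 2 measured members, of which 1 was higher (ribosomal protein L4, 0.03) and 1 lower (-0.01, a match to a mitochondrial ribosomal protein that the search pattern also took). Heat shock and endoplasmic reticulum stress had 2 measured members, both with positive means and both on sequences that the design marks as reversed (the Hsp70 match at 0.06, and 0.03 for HSPC163, taken by its letters alone). Neuropeptides and peptide hormones had 1 measured gene, the neuropeptide precursor. In all 3 lists, 0 members passed the threshold over all probes or adjusted over the list alone. Another 8 lists had a match on the array but 0 measured members: immediate early and memory-related transcription factors, sodium, calcium and mechanosensitive channels, synaptic vesicle release and cell adhesion (both by letters inside other words only), muscle, connective tissue, haemocytes and reference genes. The search patterns of the remaining 12 matched 0 probes, and these were glutamate receptors, GABA and glycine, acetylcholine, serotonin and other amines, neuropeptide processing, potassium channels, growth factors, cAMP and kinase signalling, ubiquitin and proteasome, translation factors, chromatin, and glia. Those patterns missed named probes of like function given above, among them ACN4PKA, AKA-1, tyrosine kinase 5, phosphorylase phosphatase and Ureb1, so 0 matches does not mean that no such gene was on the array. Cornichon, an auxiliary protein of glutamate receptors, was therefore not analysed here by name.

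Among probes without a gene name, the files give only the accession of an expressed sequence tag (EST). The probe for EB255735.1 had the smallest p of all probes, with a log2 ratio of -0.97 (SE 0.11, adjusted p = 0.377, limma), lower in trained animals on all 8 arrays, and its second probe was at -0.91. The probe with the smallest p stood between -1.70 and -1.23 on replicates 1, 3, 4 and 6 (trained in Cy5). On replicates 2, 5, 7 and 8 (trained in Cy3) it stood between -0.94 and -0.12. The dye term takes up this gap, so the SE is small beside the spread over arrays (SD 0.56). EB249996.1 was at -0.45 (SE 0.07, adjusted p = 0.817, limma) and also lower on all 8 arrays, with its second probe at -0.40. EB311389.1 was at 0.70 (SE 0.10, adjusted p = 0.759, limma) and its other probe at 0.67. EB342379.1 was at 0.60 (SE 0.09, adjusted p = 0.817, limma), and its 3 probes ranged from 0.54 to 0.60. Both of these were higher in trained animals on all 8 arrays. None of the 4 passed the threshold.

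**Figure D2:**
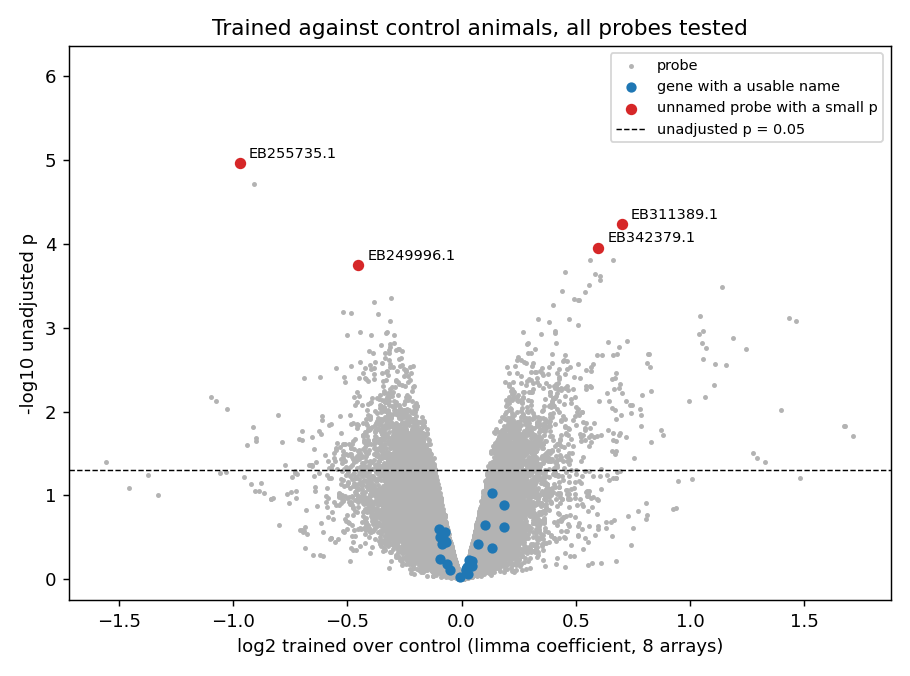
Each point is 1 of the 38970 probes tested, with its log2 ratio of trained over control on the horizontal axis and -log10 of its unadjusted p on the vertical axis (limma, 8 arrays). Named genes (blue) lie near 0, and the 4 labelled EST accessions (red) lie high on the plot without passing the adjusted threshold.

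Over all 38970 probes tested, limma called 0 past an adjusted p of 0.05, 0 higher and 0 lower in trained animals, and 0 at an adjusted p of 0.1. At an unadjusted p under 0.05 there were 2343 probes (6.01% of those tested), 1103 higher and 1240 lower. Median centring in place of loess gave 2875 such probes, 631 higher and 2244 lower, and the scanner software's processed signals gave 589 higher and 2135 lower, with 0 past the adjusted threshold in both. The median 95% interval of a probe reached 0.20 log2 units to either side of its estimate. In the main fit the whole interval lay within 0.5 log2 units of 0 for 84.0% of probes. For dim probes this does not bound the true difference, as their estimates and SE depended on the processing. Villin was at -0.07 (SE 0.06) in the main fit but at -0.55 (SE 0.26) with the processed signals. Ribosomal protein L4 went from 0.03 (SE 0.06) to 0.25 (SE 0.24), while NFASC stayed near 0 (-0.0086, SE 0.19). The share was not computed for other processing. When known differences were added to 200 of the measured probes, 50 per size, 44% of those with 0.5 log2 units and 92% of those with 1 log2 unit were recovered. In the simulated data the shares were 46% and 80%. These shares hold for many probes moved together, most of them by 1 log2 unit or more, which eases the adjusted threshold. For a difference in only a few transcripts they are too high. A difference of 0.5 log2 units or less there was often not detectable with 8 arrays. Even an estimate near 1 log2 unit could fail to pass, as EB255735.1 did at -0.97 (SE 0.11, adjusted p = 0.377, limma), though its single arrays ranged from -1.70 to -0.12. Reading trained RNA as Cy5 on every array, as the labelling text has it, called 81 probes, against 80 probes that differed between the dyes themselves, and in that reading dye and training cannot be told apart. Leaving out replicate 1 raised the count at an unadjusted p under 0.05 to 5516, still with 0 past an adjusted p of 0.05, and leaving out replicate 4, 6, 7 or 8 lowered it to between 1181 and 1476.

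Ratios of trained over control were not alike between arrays. Over the 28 pairs of arrays, the correlation across probes, which are not independent replicates, had a median of 0.0349, ranged from -0.520 (replicates 1 and 5) to 0.486 (replicates 4 and 6), and was below 0 in 14 pairs. Dye differences were not removed here, and they lower the correlation of arrays with opposite dye orientation. Replicates 1 and 5 also share number 789 in Cy5, as trained and as control, so a single animal would give a negative value there. The profiles of number 789 correlated at 0.451, within the 0.335 to 0.485 of other Cy5 pairs of high number, which leaves this open. When the channels were separated into 16 profiles, 1 axis held 40.7% of the variance. On that axis the 8 profiles of animals numbered 762 to 778 in the labels all lay below 0, and 7 of 8 profiles of animals numbered 779 to 796 lay above 0, the exception being animal 788 (replicate 5, trained) at -0.0326. Trained minus control animals gave no difference past the threshold on this axis (mean difference -0.0652, p = 0.531, exact permutation of signs over the 8 arrays, two-sided). By number, replicates 1 and 3 paired an animal up to 778 with one from 779, in opposite directions of training. On the axis itself, replicate 5 also paired a profile below 0 (trained, -0.0326) with one above 0 (control, 0.269). Both of its animals have numbers above 778, so the step in number does not cover that array.

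**Figure D3:**
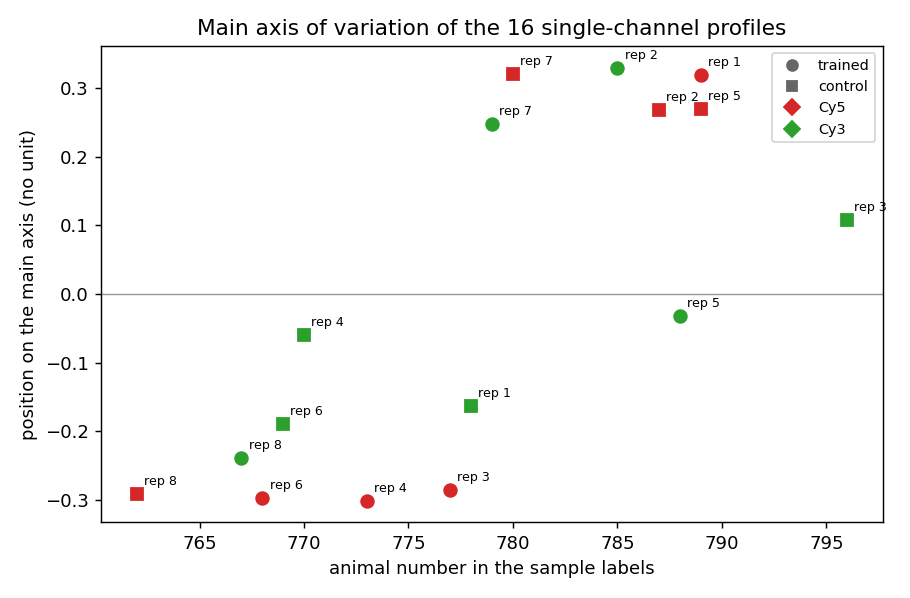
Position of the 16 single-channel profiles on their main axis of variation (vertical, no unit) against the animal number in the labels (horizontal), with circles for trained, squares for control, red for Cy5 and green for Cy3. Profiles of animals numbered up to 778 lie between -0.301 and -0.0596, and those from 779 lie between -0.0326 and 0.330.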

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

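The values of 8 arrays were searched for one that lies apart from the rest in 31 measures, and 2 were found, where chance alone gives about 1 in 20. The spike-in slope of replicate 8 was 0.824, against 0.880 to 0.910 on the other arrays. The match to BAI1-associated protein 1 had a log2 ratio of trained over control of -0.57 on replicate 5, against -0.18 to 0.15 on the others. No explanation was tested for either.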

How the results depend on the processing

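Fits with the step in animal number, with averaged sequences or gene names, and without pairs of arrays were chosen after seeing the data. In 13 of 13 alternatives of processing and model that used all arrays and the labelled direction, 0 probes passed (smallest adjusted p 0.131 with array weights). They had from 1254 probes (slide row as a term) to 6050 (array weights) at an unadjusted p under 0.05, against 2343 in the main fit. Leaving out each replicate gave 0 probes changed, 0 higher and 0 lower each time, though 19 reached an adjusted p of 0.1 without replicate 1. Averaging identical sequences or gene names gave 0. The number of lists shifted and of named probes past the threshold stayed at 0 in each setting (camera). For oxidative phosphorylation, limma's fry for changes in either direction gave an adjusted p of 0.397 with all arrays, 0.0042 with trained read as Cy5, 0.030 without replicate 1 and 0.0039 without replicates 1 and 3. Counts moved in 3 settings. Reading trained as Cy5 on every array gave 81 probes (60 higher, 21 lower), which by construction takes in the dye difference. Leaving out replicates 1 and 5 gave 7 (6 higher, 1 lower), and the unadjusted threshold gave 2343 (1103 higher, 1240 lower). Signal over background limits what can be tested: no filter on dim probes tested 61615 and a strict one 27256.

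Of 609 values of single named genes under alternatives, 0 passed the threshold and 63 had the sign turned, and the cause was not tested. With trained read as Cy5 these were dentin sialophosphoprotein -0.15, neuropeptide precursor -0.056, ribosomal protein L4 -0.051, Bcl9l -0.11, NFASC -0.0050, BAI1-associated protein 1 0.089, villin 0.0083, dar1 0.054, katanin p80 0.059, the sodium/hydrogen exchanger 0.15, phosphorylase phosphatase 0.36 and DSC-2 0.11. With median centring these were LOC100861465 -0.024, neuropeptide precursor -0.054, Ureb1 -0.057, caudal -0.13, orthodenticle -0.0075 and ACN4PKA -0.097. With processed signals these were NFASC -0.0086, DSC-2 0.049 and ACN4PKA -0.030. With offset 16 it was DSC-2 0.013. With array weights it was Bcl9l -0.0019. In slide row 1 alone these were dentin sialophosphoprotein -0.030, Ureb1 -0.093, Bcl9l -0.034, orthodenticle -0.062, BAI1-associated protein 1 0.030, AKA-1 0.24, WIG-1 0.18 and phosphorylase phosphatase 0.021. In slide row 2 alone these were the testis protein -0.0012, Bcl9l -0.011, NFASC -0.024, the sodium/hydrogen exchanger 0.0094, WIG-1 0.078 and DSC-2 0.017. With slide row as a term these were Bcl9l -0.023, AKA-1 0.024 and WIG-1 0.13. Without replicates 1 and 5 these were Bcl9l -0.0014 and phosphorylase phosphatase 0.072. Without replicates 1 and 3 these were the testis protein -0.019 and neuropeptide precursor -0.0031. Leaving out 1 replicate at a time moved neuropeptide precursor between -0.0085 and 0.24, Ureb1 between -0.022 and 0.080, caudal between -0.020 and 0.11, Bcl9l between -0.018 and 0.051, orthodenticle between -0.015 and 0.048, NFASC between -0.018 and 0.072, AKA-1 between -0.21 and 0.0096, WIG-1 between -0.17 and 0.0018, phosphorylase phosphatase between -0.17 and 0.073, DSC-2 between -0.055 and 0.031 and ACN4PKA between -0.055 and 0.15. Without a turn of sign, sterolin-2 ranged from 0.033 to 0.15, the testis protein from 0.021 to 0.11, ribosomal protein L4 from 0.0066 to 0.057, BAI1-associated protein 1 from -0.15 to -0.036, katanin p80 from -0.13 to -0.035, the sodium/hydrogen exchanger from -0.096 to -0.020 and doublesex from -0.13 to -0.0064. In the same fits tyrosine kinase 5 ranged from 0.12 to 0.30, dentin sialophosphoprotein from 0.12 to 0.27 and LOC100861465 from 0.092 to 0.18. Villin ranged from -0.095 to -0.045 and dar1 from -0.15 to -0.059.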

Other observations

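Tests of the animal number, of a hybridisation difference within arrays and of the step in number as a term were chosen after their results had been seen, as were the fits without pairs of arrays. The reading of 4 tests, on exchanged labels in 1 array, on exchanged labels in replicate 1 or 5, on the choice of which arrays to leave out and on the step in number as a term, was changed after their values were seen, for the first and the last more than once, and the first is given here by the bound set beforehand.

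Without replicates 1 and 5, whose labels share the animal number 789, 7 probes of 4 EST accessions passed limma's threshold on 6 arrays. They are named here after their values were seen. All 3 probes of EB244298.1 were higher in trained animals on 6 of 6 arrays (log2 ratio 1.39, SE 0.09, adjusted p = 0.025, limma, for the probe with the smallest SE), and that probe stood at 0.09 and 0.06 on replicates 1 and 5, close to 0. It was at 1.82, 2.18 and 1.87 on replicates 3, 4 and 6 (trained in Cy5). On replicates 2, 7 and 8 (trained in Cy3) it was at 0.50, 1.07 and 0.86. The dye term takes up this gap, so the SE is small beside the spread over arrays (SD 0.66). All 7 probes were further from 0 on replicates 3, 4 and 6 than on replicates 2, 7 and 8. For EB324506.1, 2 of its 3 probes passed (1.53 and 1.54, each with SE 0.14 and adjusted p = 0.041, limma), with -0.083 and -0.26 on replicate 1 and 0.39 and 0.25 on replicate 5. For EB234048.1, 1 of its 2 probes passed and was lower on 6 of 6 arrays (-0.87, SE 0.06, adjusted p = 0.025, limma), but higher on replicates 1 and 5 (0.25 and 0.63), and its other probe was at -0.70. For EB245940.1, 1 of its 3 probes passed and was at 1.13 (SE 0.10, adjusted p = 0.041, limma), but at -0.35 and -0.12 on replicates 1 and 5. With all 8 arrays the adjusted p of each of the 7 probes was 0.817. The estimates were then 1.05 to 1.07 for EB244298.1, 1.19 and 1.16 for EB324506.1 and 0.79 for EB245940.1, with larger SE (0.22 to 0.28). EB234048.1 was at -0.55 (SE 0.20).

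Of the 28 pairs of arrays that can be left out, 1 gave as many probes, this pair, and 2 others (replicates 1 and 6, and 1 and 7) gave 3 each, but the pair was picked after the data were seen and replicates 1 and 5 also had the lowest array weights (0.416 and 0.543), so this share, read beforehand as speaking against the choice of pair, decides nothing. An exchange of trained and control in the labels of replicate 1 may be considered, since its ratios correlated at -0.482 across probes with the effect fitted on the other arrays (replicates 2 to 8 lay between -0.157 and 0.352), which by the bound set beforehand would speak for an exchange. A candidate explanation in its place is that replicate 1 compares animals from either side of the step in number. It was tested by regressing out the main axis of the 16 profiles, which gave a correlation of 0.0695. But that axis was made from the same profiles, and Cy5 over Cy3 of replicate 1 correlated with it at 0.775. Removing the axis takes out much of this array's signal under either cause, so the test cannot decide between them. The bound for that test was written after the raw correlation was known, and replicate 5 stood at -0.256 in the same test, so exchanged labels cannot be told apart from animal origin here. With 6 arrays only 10 splits exist, too few for a share under 0.05, and the labelled split gave 7 probes (1 of the 10 splits gave as many) against 2 in the highest other.

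The main axis of the single-channel profiles may follow the origin of the animals. The labels say that animals came from at least 2 shipments without tying numbers to them, so a change of shipment between numbers 778 and 779 is a hypothesis. The largest gap in mean position over 9 possible steps in number was 0.457, and permuting the number pairs over arrays in all 40320 ways gave p = 0.00208 (exact permutation test, 8 arrays). A hybridisation difference shared by both channels of an array cancels in Cy5 over Cy3. Such ratios of replicates 1 and 3 correlated at -0.409 across probes, which argues against it as the only source of the axis on these arrays. On the others both animals lie on the same side of the step, so array and number cannot be told apart there. Slide rows differed by -0.0537 in mean position (p = 0.714, exact permutation test, 8 arrays), small beside a range of 0.631. Age, season or housing of the animals stay open, as none was tested.

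At an unadjusted p under 0.05 with limma, 10 of 35 splits of the arrays reached the 2343 probes of the labelled one, so chance cannot be excluded for that count. The highest other gave 7710, several times as many, with replicates 1, 5, 7 and 8 against the rest, and what this split reflects was not tested. For the 0 probes past the threshold and the 0 lists shifted, 35 of 35 splits gave as many, with 8 and 0 in the highest other, but a count of 0 fixes this outcome and it says nothing about chance. Turning the direction of 1 array at a time gave at most 0 probes past the threshold. By the bound set beforehand this speaks against a wrong label in 1 array, but the test cannot decide it. The fit passed 0 probes even for EB255735.1 at -0.97, and turning replicate 1 lowered the smallest adjusted p from 0.377 to 0.061 (limma). At an unadjusted p under 0.05 the highest counts were 6794, 3180 and 3058 with replicates 1, 2 and 5 turned, and the first restates that replicate 1 opposes the other arrays. The step in animal number as a term left 0 probes past the threshold, and 2909 at an unadjusted p under 0.05 against 2343 without it. The term acts only on replicates 1 and 3, in opposite directions, so it left the estimates unchanged (LOC100861465 at 0.14 in both fits). It could alter only their spread, so it cannot decide whether differences across the step hide a difference with training. Leaving out replicates 1 and 3, which span the step, gave 5373 (over 1.5 times the labelled count, a criterion chosen afterwards). However, leaving out replicate 1 alone gave 5516 and replicate 3 alone 2435, and as no bound was set beforehand the question stays open.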
